A study of Mus musculus with 9 samples.

How the data were processed

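Gene expression was measured by RNA-seq of total RNA from 9 libraries of primary mouse embryonic fibroblasts, all labelled D4-OSKM-2ndMEFs. They were 3 each of control, Zscan4f overexpression and Zscan4f3A overexpression. The groups and replicate numbers were taken from the labels, and nothing in the labels pairs the samples. Libraries whose title names no overexpression were taken as control. The authors aligned reads with HISAT2 2.1.0 and estimated abundance with StringTie, whose version is not given in the sources used here. The TPM values were made by the authors per kilobase of transcript and scaled to the same sum in each library. The FPKM values were made by the authors per kilobase of transcript and scaled by the fragments of the library. The coverage values, made by the authors with StringTie, are the mean read depth over a gene without correction for sequencing depth. No counts were used, since the files hold none. The genome build and the annotation release are not given in the sources used here. Of 54986 gene IDs in the files, 54079 were found in the GRCm38 reference annotation, and 97.7% of these had identical chromosome, start and end, so coordinates are given on GRCm38. The 15 gene IDs with more than 1 entry in a library were summed, and 659 gene names carried by more than 1 gene ID were kept apart by ID. None of the 36 pairs of libraries held identical values (0).

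Aligned sequence per library was estimated from the commonest ratio of coverage to FPKM, which is proportional to depth, and ran from 3.31 to 8.39 gigabases. Without counts no counting interval could be given, so precision is stated as the SD over 3 libraries.

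All tests were run in R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes with TPM of at least 1 in at least 3 of the 9 libraries were kept (15837 genes), and log2(TPM + 1) was fitted with limma (group means, empirical Bayes with a trend of the prior variance on expression). The 3 comparisons were Zscan4f against control, Zscan4f3A against control and Zscan4f against Zscan4f3A, each two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Log2 fold changes and their SE come from this fit, while TPM means and SD are on the plain scale. Genes called against both other groups with the same sign were counted from the same fit. The covariance of the comparisons against control was set beside 100 simulations of unchanged groups that shared a redrawn control group. Each simulation mixed the residuals of the fit with the same random weights for every gene. Genes that varied together thus still did so, and a single draw could move many genes at once. Overlap and signs of called genes were set beside 100 simulations that kept the Zscan4f means and set Zscan4f3A to the control mean, and overlap also beside that of independent lists.

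The tests, the alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. Lists with at least 5 tested members (28 of 31) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The lists of two-cell-stage, germline and macrophage genes had fewer tested members and are given as values. Camera with an estimated correlation and fry were alternatives, and each list's count of changed members was also adjusted over the list alone. Named genes were the Zscan4 genes, and in each comparison the 10 largest rises and 10 largest falls in log2 fold change among called genes. These needed a mean TPM of at least 5 in the higher group and no overlap between the 3 libraries of each group, and unnamed loci, predicted genes, ribosomal RNA and small RNA genes were left out. Up to 4 members with the smallest p per list, and Tet1, Tet2, Tet3, Pou5f1, Sox2, Klf4 and Myc, were named as well.

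Alternatives were a pseudocount of 0.1, no filter, a filter at TPM of 5, FPKM, median-of-ratios scaling, quantile normalization, a fit of only the 2 groups compared, no trend, a robust prior variance, the replicate number as a block, a fold change of at least 1.5 and leaving out each library in turn. Chosen after the data were seen were library quality weights, protein-coding genes alone, the fit of Zscan4f against control without Zscan4f3A replicate 3, and the count of genes changed alike in both comparisons against control. The code was tested on simulated data with 200 changed genes among 15837. The 200 were drawn from genes with a mean log2(TPM + 1) above that of 5 TPM. The code recovered 61.6% of them at a log2 change of 0.5 and 93.9% at 1, and called 12 unchanged genes. Camera found the shifted gene list (adjusted p = 5.5e-41) and called 0 other lists. Noise was drawn independently for each gene, so this cannot show how camera fares with correlated genes. Nor do the shares recovered cover genes of lower expression.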

Results

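Total RNA from primary mouse embryonic fibroblasts of the C57BL/6 strain, labelled D4-OSKM-2ndMEFs, was sequenced in 9 libraries. The libraries fell into 3 groups of 3: control, Zscan4f overexpression and Zscan4f3A overexpression. The titles of the control libraries name neither an overexpressed gene nor an empty vector. Changes against control may therefore include effects of overexpression as such. All of them, control included, carry OSKM in the label, so no group without it was sequenced. Zscan4f belongs to a cluster of related zinc finger genes on chromosome 7 that are known for brief expression at the two-cell stage of the mouse embryo and in embryonic stem cells. Zscan4f3A is a variant of it by its label, and the sources used here do not give its sequence or the meaning of D4. The aligned sequence behind the libraries was 7.79, 8.26 and 6.60 gigabases in the control libraries, 8.39, 7.48 and 8.10 in the Zscan4f libraries and 6.93, 8.38 and 3.31 in the Zscan4f3A libraries. Zscan4f3A replicate 3 thus had the lowest depth. The files hold no counts, so the number of fragments behind a single value is unknown and its precision is given by the SD of 3 libraries. Nothing states that the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

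The Zscan4 cluster was read first, since it shows whether the labels fit. Zscan4f (ENSMUSG00000070828.10, chromosome 7, 11397915 to 11402318 on GRCm38) stood at 0.430 ± 0.488 TPM in control, at 564 ± 6.18 with Zscan4f and at 772 ± 102 with Zscan4f3A (SD, n = 3 each). All 3 control libraries lay at 0.96 TPM or below. Signal also appeared at neighbouring loci of the cluster, whose sequences are closely related. Zscan4c reached 117, 118 and 113 TPM in the Zscan4f libraries and 188, 191 and 0 in the Zscan4f3A libraries. Zscan4d stood at 15.3, 13.97 and 13.9 TPM with Zscan4f and at 24.9, 26.0 and 0 with Zscan4f3A, and Zscan4e at 16.6, 19.0 and 15.6 against 35.2, 38.3 and 0. The unnamed locus RP24-351P7.3 of the same cluster held 167, 29.2 and 0 TPM in the Zscan4f libraries and 270.0, 271 and 274 in the Zscan4f3A libraries. Zscan4f3A replicate 3 was thus listed at 0 for Zscan4c, Zscan4d and Zscan4e while Zscan4f itself stood at 654 TPM in it. Summed over 8 loci of the cluster, 3 of them unnamed, the signal was 0.619 ± 0.718 TPM in control, 841 ± 97.3 with Zscan4f and 1285 ± 309 with Zscan4f3A. That sum was chosen after the values were seen.

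**Figure D1:**
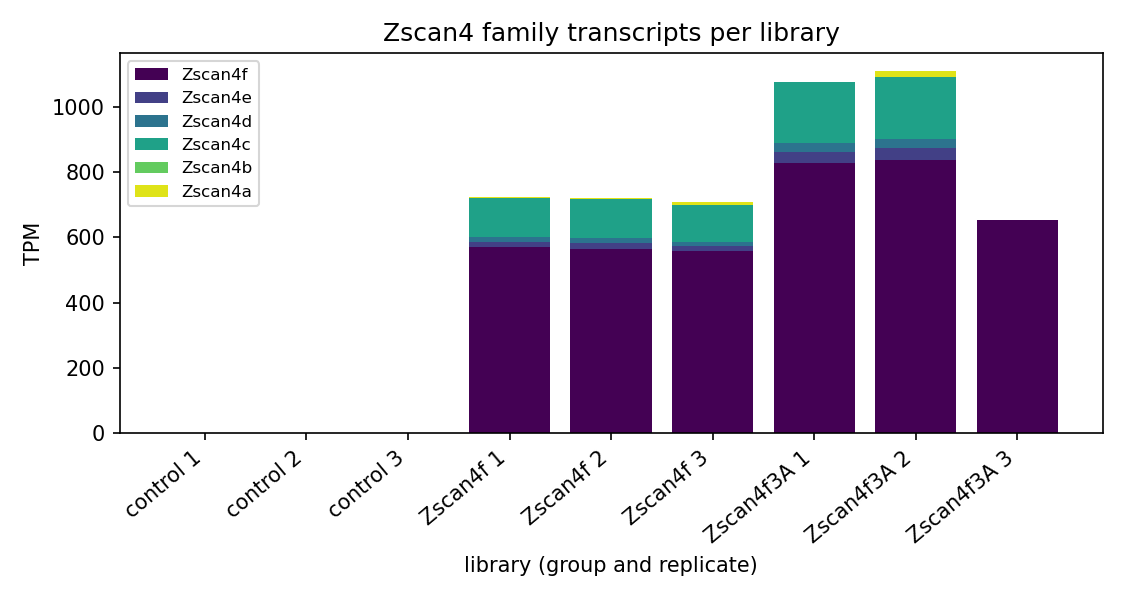
Stacked bars give the TPM of Zscan4a to Zscan4f in each of the 9 libraries, named by group and replicate. The control libraries are near 0, and Zscan4f3A replicate 3 shows Zscan4f (654 TPM) without Zscan4c, Zscan4d or Zscan4e.

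With Zscan4f overexpression, epithelial genes and the genes of cholesterol synthesis, glycolysis and the proteasome were higher than in control, and contractile genes and elastin were lower. Krt8 (ENSMUSG00000049382.10, chromosome 15, 101996698 to 102004482), a keratin of simple epithelia, rose from 20.2 ± 1.20 to 78.5 ± 1.88 TPM. Klk10 (ENSMUSG00000030693.10, chromosome 7, 43781035 to 43785410), a kallikrein-related peptidase, rose from 26.9 ± 0.640 to 137 ± 7.55 TPM, a log2 fold change of 2.30 (SE 0.05, adjusted p = 1.0e-07). Eln (ENSMUSG00000029675.12, chromosome 5, 134702593 to 134747323), which encodes elastin, fell from 81.3 ± 3.13 to 20.1 ± 0.650 TPM, a log2 fold change of -1.97 (SE 0.05, adjusted p = 1.6e-07; n = 3 for each group). By limma, 2922 of 15837 genes changed, 1384 higher and 1538 lower, and 4923 had an unadjusted p under 0.05. The fold change was at least 1.5 in 891 of the 2922 genes.

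The largest rises by the rule for named genes were those of Zscan4f, Zscan4c, Zscan4e, Zscan4d, Klk10, Fndc3c1, Sptssb, Klk13, Lrrc26 and Krt8. Sptssb, a subunit of serine palmitoyltransferase, rose from 1.34 ± 0.157 to 9.02 ± 0.523 TPM, and Klk13, another kallikrein-related peptidase, from 2.52 ± 0.555 to 13.5 ± 1.43. Fndc3c1 rose from 0.944 ± 0.229 to 8.26 ± 0.534 TPM and Lrrc26, an auxiliary subunit of potassium channels, from 1.82 ± 0.554 to 10.2 ± 1.43. Zscan4c rose by 6.72 on the log2 scale (SE 1.73, adjusted p = 0.028), Zscan4d by 3.94 (SE 1.08, 0.036) and Zscan4e by 4.12 (SE 1.20, 0.046). These SE include the values of 0 in Zscan4f3A replicate 3, and in a fit of only the 2 groups compared the adjusted p was 3.61e-06, 5.04e-06 and 7.73e-06. In the fit of all groups each call was lost without any 1 of the 6 libraries compared, with adjusted p from 0.0692 to 0.117. The sequences of Zscan4c, Zscan4d and Zscan4e are closely related to that of Zscan4f. The values do not tell their own RNA from Zscan4f reads assigned to them, so a response of these genes is not shown. The largest falls were those of Islr, Tbkbp1, Ptk2b, Nipsnap1, mt-Atp6, Eln, Steap3, Capn6, Nt5e and Erg. Islr, a secreted protein of stromal cells, fell from 7.13 ± 0.227 to 0.468 ± 0.204 TPM. Ptk2b, a tyrosine kinase related to focal adhesion kinase, fell from 24.9 ± 0.253 to 4.45 ± 0.317 TPM, and Capn6, of the calpain family, from 98.0 ± 5.02 to 25.2 ± 1.47. Nt5e, the surface enzyme CD73, fell from 11.7 ± 1.18 to 2.47 ± 0.422 TPM, and Steap3, a ferrireductase, from 15.6 ± 0.773 to 3.34 ± 0.156. For mt-Atp6 the control libraries themselves ranged from 5812 to 10007 TPM, against 1740.0 to 1748 in the Zscan4f libraries.

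Of the 28 gene lists tested, 14 were called by camera with Zscan4f against control, 11 up and 3 down. With an estimated correlation 8 of the 14 held, at adjusted p from 0.0032 (epithelial genes) to 0.040 (proteasome). List adjusted p are given at the preset correlation unless stated otherwise. Member numbers are those that passed the filter on low values, unless stated otherwise. Of 30 epithelial genes 18 passed it. Among these 18, 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 0.89 and a list adjusted p of 7.4e-12. Dsp, the desmosomal protein desmoplakin, rose from 58.9 ± 1.75 to 112 ± 5.31 TPM, Epcam, an epithelial adhesion molecule, from 1.38 ± 0.459 to 6.53 ± 0.671, and St14, the membrane protease matriptase, from 4.36 ± 0.366 to 11.1 ± 0.398. Of 9 keratinocyte markers tested, from a list of 14, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a list adjusted p of 0.0016. That list was not called with adjusted p = 0.15 with an estimated correlation. Its risers included Krt14, a keratin of basal epidermis, from 28.4 ± 1.32 to 85.3 ± 4.07 TPM, and Krt16, from 60.4 ± 0.454 to 95.9 ± 1.54.

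Of 24 genes of the cholesterol synthesis list, 17 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.36 and a list adjusted p of 3.0e-12. Fdps, which makes farnesyl diphosphate, rose from 215 ± 3.89 to 329 ± 17.2 TPM. Cyp51, a sterol demethylase, rose from 93.6 ± 2.24 to 122 ± 2.58 TPM. In the glycolysis list 12 of 25 genes rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.35 and a list adjusted p of 1.4e-06. Eno3, an enolase best known from muscle, rose from 29.4 ± 1.90 to 78.8 ± 8.01 TPM, Pkm, pyruvate kinase, from 1172 ± 21.8 to 1805 ± 49.2, and Pgk1, phosphoglycerate kinase, from 357 ± 8.97 to 465 ± 2.79. Subunits of the proteasome core and regulatory particle moved by less: 20 of 33 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.21 and a list adjusted p of 1.6e-10. Psmd14, the deubiquitinase of the lid, rose from 137 ± 7.07 to 172 ± 1.38 TPM and Psma1, of the core, from 183 ± 5.39 to 228 ± 1.62. The immunoproteasome, activator and assembly list had 2 of 13 members higher and 0 lower (2 and 0 adjusted over the list alone), with a list adjusted p of 0.041. This last call was lost with adjusted p = 0.38 with an estimated correlation, and with adjusted p of 0.0513, 0.0791, 0.0642 and 0.0898 without control replicate 2, control replicate 3, Zscan4f replicate 1 and Zscan4f replicate 2.

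Fibroblast and mesenchymal genes moved mostly down: of 37, 18 fell and 5 rose (20 and 9 adjusted over the list alone), with a median log2 fold change of -0.17 and a list adjusted p of 3.6e-04. The list was not called with adjusted p = 0.087 with an estimated correlation. Loxl1, a lysyl oxidase of elastic fibres, fell from 164 ± 2.96 to 74.0 ± 2.60 TPM, Col6a2, a chain of collagen VI, from 159 ± 3.74 to 89.0 ± 2.21, and Cdh2, N-cadherin, from 128 ± 2.55 to 69.2 ± 1.28. Among 13 contractile myofibroblast genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.32 and a list adjusted p of 1.7e-07. Tpm2, a tropomyosin, fell from 282 ± 5.74 to 206 ± 5.90 TPM, and Ctgf, a secreted matricellular factor, from 478 ± 16.9 to 339 ± 8.42.

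In the cell division list, 11 of 40 genes rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.19 and a list adjusted p of 7.1e-06. Its members with the smallest p were genes of DNA replication and nucleotide supply: Rrm2 rose from 33.0 ± 2.20 to 46.2 ± 1.5 TPM, Pcna from 109.6 ± 1.93 to 128 ± 2.73 and Mcm2 from 17.5 ± 1.80 to 23.4 ± 0.656. Of 25 p53 targets and senescence genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a list adjusted p of 0.0082 and adjusted p = 0.087 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, fell from 935 ± 29.9 to 791 ± 22.3 TPM and Sesn1 from 25.5 ± 1.25 to 17.1 ± 0.0375, while Btg2 rose from 67.2 ± 1.75 to 88.1 ± 2.24. Of 28 heat shock proteins and chaperonins, 8 rose and 1 fell (10 and 1 adjusted over the list alone; list adjusted p = 0.0011), Cct3, a chaperonin subunit, from 204 ± 3.71 to 243 ± 5.02 TPM. Of 32 interferon response genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone; list adjusted p = 0.0041), among them Bst2, from 33.0 ± 2.19 to 46.7 ± 2.71 TPM, and Gbp3, from 7.21 ± 0.814 to 12.3 ± 1.28. Cytosolic ribosomal proteins (5 of 56 higher, 0 lower; 2 and 0 adjusted over the list alone) had a list adjusted p of 0.0011, and adjusted p = 0.38 with an estimated correlation. The nuclear genes of oxidative phosphorylation (7 of 58 higher, 0 lower; 1 and 0 adjusted over the list alone) had a list adjusted p of 0.011, adjusted p = 0.16 with an estimated correlation and adjusted p = 0.067 without Zscan4f replicate 2.

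The other 14 lists were not called. Of 13 mitochondrially encoded genes, mt-Nd1 was higher (adjusted p = 0.017, and up to 0.0624 with 1 library left out) and mt-Atp6 lower (list adjusted p = 0.48; 1 and 1 also adjusted over the list alone), and the tricarboxylic acid cycle had 1 of 21 higher, Cs, and 1 lower, Pcx (0.091; 1 and 1). The DNA methylation list (1 of 22 higher, 2 lower; list adjusted p = 0.48; 1 and 2 adjusted over the list alone) held Idh2, higher, and Tet2 and Cxxc5, lower. Telomere maintenance had 2 of 22 higher and 1 lower (list adjusted p = 0.48; 2 and 1 adjusted over the list alone). For inflammatory secreted factors 3 of 22 were higher and 2 lower (list adjusted p = 0.13; 4 and 2 adjusted over the list alone), and both Ptgs2, from 42.2 ± 1.27 to 73.4 ± 0.474 TPM, and Ccl2, from 144 ± 3.25 to 219 ± 2.34, rose. The unfolded protein response had 1 of 30 higher and 0 lower (0.13; 1 and 0 adjusted over the list alone), and hypoxia response 6 of 22 higher and 4 lower (0.16; 6 and 4).

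Lists of markers for the cell types below were not called as lists, although single markers were. Of 10 neural markers 6 were higher and 2 lower (list adjusted p = 0.069; 7 and 2 adjusted over the list alone): Nes rose from 30.9 ± 1.65 to 79.0 ± 2.94 TPM and Gap43 fell from 196 ± 6.97 to 109 ± 4.96. Trophoblast and extraembryonic endoderm markers had 0 of 7 higher and 2 lower, Lamb1 and Sparc (0.053; 0 and 2 adjusted over the list alone). Endothelial markers had 2 of 5 higher, Tek and Flt1, and 1 lower, Erg (0.46; 2 and 1), and their test pointed up while the median log2 fold change of -0.04 and the mean of -0.17 pointed down. Skeletal muscle markers had 1 of 6 higher and 0 lower (0.56; 1 and 1 adjusted over the list alone), chondrocyte and osteoblast markers 1 of 8 higher and 2 lower (0.56; 1 and 2), and adipocyte markers 1 of 5 higher and 1 lower (0.61; 1 and 1). Macrophage markers had 4 of 16 members tested, too few for a list test. Of these Cd68 rose from 12 ± 0.967 to 18.7 ± 1.39 TPM, and Cd14 stood at 3.69 ± 0.437 and 2.5 ± 0.229 (adjusted p = 0.044, and 0.0723 to 0.139 with 1 library left out).

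No tested gene of the two-cell stage, the germline or pluripotency rose with Zscan4f. Of 36 two-cell-stage genes other than Zscan4, 24 were in the files under the names used and 1 passed the filter on low values: Ddit4l fell from 28.2 ± 2.45 to 17.4 ± 2.25 TPM (adjusted p = 0.0026). The other 23 stayed at or below 0.798 TPM in every library, and 8 of them were listed at 0 throughout. Of 27 germline genes 3 were tested and 0 changed, and the highest of the others was Brdt at 1.24 TPM. Of 35 pluripotency genes 7 were tested, 0 rose and 1 fell (0 and 3 adjusted over the list alone; list adjusted p = 0.074). The 1 was Sox2, which fell from 574 ± 33.5 to 472 ± 24.3 TPM, a log2 fold change of -0.28 (SE 0.06, adjusted p = 0.0090). Pou5f1 stood at 15.8 ± 2.26 and 13.9 ± 1.57 TPM (adjusted p = 0.34), Klf4 at 286 ± 29.6 and 273 ± 18.2 (0.68) and Myc at 55.8 ± 1.47 and 58.6 ± 0.717 (0.65). Values per gene do not part transgene RNA from that of the cell's own gene.

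Tet2, the gene named in the title of the series, encodes an enzyme that oxidises 5-methylcytosine. Tet2 (ENSMUSG00000040943.12, chromosome 3, 133463679 to 133545139) fell with Zscan4f from 28.3 ± 2.93 to 19.3 ± 0.942 TPM, a log2 fold change of -0.53 (SE 0.08, adjusted p = 0.0024). With Zscan4f3A it stood at 22.5 ± 1.19 TPM, with adjusted p = 0.40 against control and 0.12 against Zscan4f. Tet1 stood at 2.76 ± 0.938 TPM in control and 2.52 ± 0.710 with Zscan4f (adjusted p = 0.89), and Tet3 at 23.5 ± 0.790 and 20.8 ± 1.30 (0.11).

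**Figure D2:**
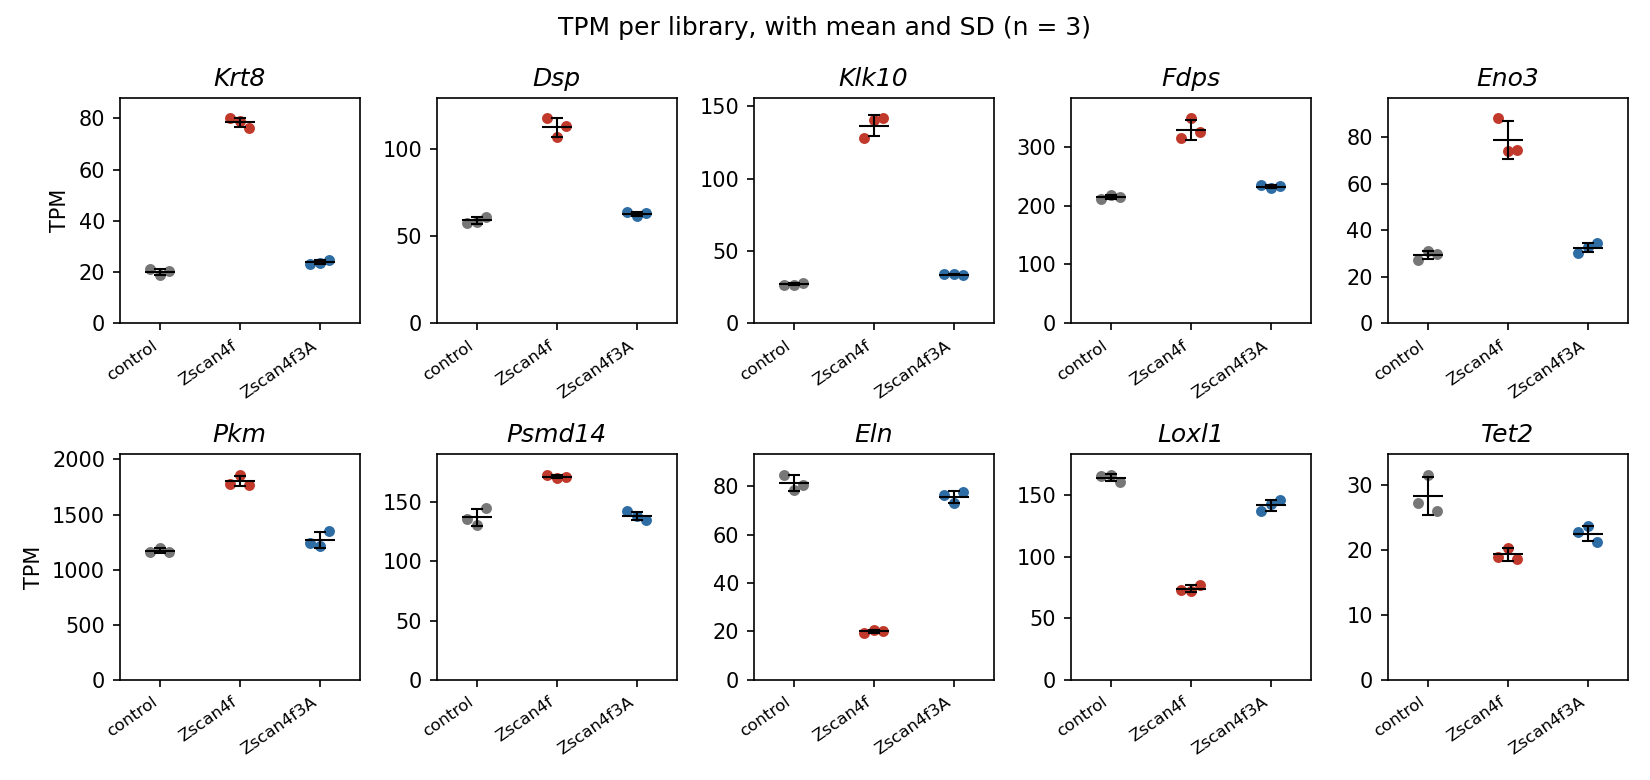
Points give the TPM of 10 genes in each library of the 3 groups, and bars the mean and SD (n = 3). Every Zscan4f library lies above all control and Zscan4f3A libraries for Krt8, Dsp, Klk10, Fdps, Eno3, Pkm and Psmd14 and below them for Eln, Loxl1 and Tet2.

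Zscan4f3A overexpression changed 5 genes against control by limma at an adjusted p under 0.05, 3 higher and 2 lower, and 1389 genes had an unadjusted p under 0.05. Apart from Zscan4f itself, Nudcd3 (chromosome 11, 6105691 to 6200415), which encodes a cochaperone of the NudC family, rose from 30.2 ± 3.07 to 55.6 ± 0.695 TPM (log2 fold change 0.86, SE 0.08, adjusted p = 0.010), and it stood at 30.5 ± 2.38 TPM with Zscan4f. Klk14 (chromosome 7, 43690418 to 43695536), a kallikrein-related peptidase, rose from 70.8 ± 0.890 to 92.4 ± 1.90 TPM (0.38, SE 0.03, adjusted p = 0.010). Emx2 (chromosome 19, 59458372 to 59465357), a homeobox transcription factor, fell from 39.6 ± 1.07 to 22.6 ± 0.452 TPM (-0.78, SE 0.06, adjusted p = 0.0042). Igfbp3 (chromosome 11, 7206086 to 7213923), a carrier of insulin-like growth factors, fell from 923 ± 9.24 to 771 ± 10.9 TPM (-0.26, SE 0.03, adjusted p = 0.018). With Zscan4f, Klk14 reached 224 ± 4.80, Emx2 17.7 ± 1.20 and Igfbp3 445 ± 7.63 TPM. The count depended on single libraries: it was 16 without Zscan4f3A replicate 3, 8 without control replicate 1, 9 without control replicate 2 and 1 without control replicate 3. It was 10 without Zscan4f replicate 3, which is outside this comparison but in the shared fit. Igfbp3 was lost without any 1 of 5 of the 6 libraries (adjusted p from 0.0754 to 0.0963). Nudcd3 (0.0558 to 0.0643) and Klk14 (0.0531 to 0.0584) were lost without control replicate 3 or Zscan4f3A replicate 1 or 2, and Emx2 (0.051) without control replicate 3. With the replicate number as a term only Zscan4f was left.

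Without Zscan4f3A replicate 3, the 16 genes also included Mal (log2 fold change 0.31, SE 0.03, adjusted p = 0.017) among the higher ones. Zscan4c, Zscan4d, Zscan4e and the unnamed loci RP24-351P7.8 and RP24-96C7.8 of the cluster were higher too. Mtss1l (-0.63, SE 0.06, adjusted p = 0.015), Gal3st4 (-1.57, SE 0.14, adjusted p = 0.0076) and AC121113.1 (-0.98, SE 0.11, adjusted p = 0.025) were among the lower ones.

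With Zscan4f3A the median log2 fold changes of the 28 lists lay between -0.07 and 0.12. Camera called 3 of 28 lists: epithelial genes up (median log2 fold change 0.09, adjusted p = 0.040), keratinocyte markers up (0.12, adjusted p = 0.040) and fibroblast and mesenchymal genes down (-0.04, adjusted p = 0.040). None of their members was called over all genes, and 1, 2 and 1 were adjusted over the list alone. All 3 list calls were lost, with adjusted p = 0.39, 0.57 and 0.44 with an estimated correlation, respectively. With 1 library left out, the adjusted p ranged from 0.0723 to 0.123 for the epithelial list, from 0.00629 to 0.231 for the keratinocyte list and from 0.0325 to 0.109 for the fibroblast list. Cholesterol synthesis (adjusted p = 0.13), glycolysis (0.24), the proteasome (0.66), contractile genes (0.98) and cell division (0.54) were not called. Sign differed between the test, the median and the mean in 6 of the 28 lists, none of them called: the immunoproteasome, mitochondrially encoded, contractile, endothelial, neural and chondrocyte and osteoblast lists.

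The contrast of Zscan4f with Zscan4f3A tests whether the 2 overexpressed forms differ in effect. Krt8 was higher with Zscan4f, at 78.5 ± 1.88 TPM against 23.9 ± 0.815, Klk10 at 137 ± 7.55 against 33.7 ± 0.226, and Entpd1, an ectonucleotidase, at 12.8 ± 0.835 against 3.89 ± 0.726. Eln was lower with Zscan4f, at 20.1 ± 0.650 TPM against 75.7 ± 2.49, Tenm3, a teneurin of the cell surface, at 20.7 ± 1.94 against 62.2 ± 1.16, and Slc38a4, an amino acid transporter, at 15.2 ± 3.26 against 52.7 ± 1.5. By limma 2395 genes differed, 1185 higher and 1210 lower with Zscan4f, and 4677 had an unadjusted p under 0.05. The count was 1574 without Zscan4f replicate 3, and 657 of the 2395 differed by at least 1.5-fold. Zscan4f itself was not called (log2 fold change -0.44, SE 0.21, adjusted p = 0.20), although each Zscan4f3A library lay above each Zscan4f library. Replicates 1 and 2 of Zscan4f3A also lay above all Zscan4f libraries in the sum of Zscan4a to Zscan4f and in that of the 8 loci, while replicate 3 lay below all of them in the first and above 2 of 3 in the other. Zscan4c, Zscan4d and Zscan4e were not called with all libraries, and without Zscan4f3A replicate 3 they were lower with Zscan4f (log2 fold change -0.70, -0.79 and -1.07).

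By the rule for named genes, the largest differences upward were those of Fndc3c1, Sptssb, Klk13, Klk10, Lrrc26, Krt8, Ly6g6c, B3gnt3, Tac1 and Entpd1. B3gnt3, a glycosyltransferase, stood at 5.94 ± 0.613 TPM with Zscan4f and 1.33 ± 0.448 with Zscan4f3A. The largest downward were those of mt-Atp6, Tbkbp1, Nipsnap1, Eln, Ptk2b, Slc38a4, Gria1, Capn6, Olfml1 and Tenm3. Gria1, a subunit of glutamate receptors, stood at 1.63 ± 0.170 TPM with Zscan4f and 7.44 ± 0.731 with Zscan4f3A, and Olfml1 at 4.14 ± 0.287 and 14.6 ± 1.30. Sox2 was lower with Zscan4f, at 472 ± 24.3 against 582 ± 27.0 TPM (adjusted p = 0.0080), while Pou5f1 (0.95), Klf4 (0.49), Myc (0.71), Tet1 (0.98) and Tet3 (0.18) were not called.

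Camera called 15 of 28 lists between Zscan4f and Zscan4f3A, 12 up and 3 down. With an estimated correlation 7 held, at adjusted p from 0.0038 (epithelial genes) to 0.049 (proteasome). Epithelial genes had 14 of 18 higher and 0 lower (14 and 0 adjusted over the list alone; list adjusted p = 2.0e-11), and cholesterol synthesis 16 of 24 and 0 (18 and 0; 9.9e-11). The proteasome had 16 of 33 higher and 0 lower (22 and 0 adjusted over the list alone; 3.4e-10), and glycolysis 11 of 25 and 1 (15 and 2; 4.6e-06). Of 40 cell division genes 13 were higher and 0 lower (16 and 0 adjusted over the list alone; 7.6e-08), among them Mki67, the proliferation antigen, at 17.9 ± 0.742 against 13.6 ± 0.239 TPM. Heat shock proteins had 6 of 28 higher and 0 lower (14 and 1 adjusted over the list alone; 1.1e-04), and contractile genes 0 of 13 higher and 8 lower (0 and 9; 2.8e-08).

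The other 8 calls were lost with an estimated correlation. Fibroblast and mesenchymal genes had 6 of 37 higher and 16 lower (9 and 18 adjusted over the list alone; list adjusted p = 0.0035; adjusted p = 0.15 with an estimated correlation). For keratinocyte markers 4 of 9 were higher and 0 lower (4 and 0 adjusted over the list alone; 0.0035; adjusted p = 0.18 with an estimated correlation). For p53 targets 1 of 25 was higher and 6 lower (1 and 9 adjusted over the list alone; 0.0036; adjusted p = 0.070 with an estimated correlation). Ribosomal proteins had 8 of 56 higher and 1 lower (10 and 1 adjusted over the list alone; 9.2e-04; adjusted p = 0.37 with an estimated correlation). The tricarboxylic acid cycle had 4 of 21 higher and 1 lower (4 and 1 adjusted over the list alone; 0.026; adjusted p = 0.11 with an estimated correlation), and without Zscan4f replicate 2 its adjusted p was 0.0568. Oxidative phosphorylation had 6 of 58 higher and 0 lower (6 and 0 adjusted over the list alone; 0.028; adjusted p = 0.22 with an estimated correlation), with adjusted p of 0.129 without Zscan4f replicate 2 and 0.0907 without Zscan4f3A replicate 3. The interferon response had 7 of 32 higher and 1 lower (8 and 1 adjusted over the list alone; 0.028; adjusted p = 0.094 with an estimated correlation), with adjusted p of 0.0521 without Zscan4f replicate 1. The immunoproteasome list had 0 of 13 called (0.038; adjusted p = 0.36 with an estimated correlation), with adjusted p of 0.0681, 0.121 and 0.17 without Zscan4f replicate 1, Zscan4f replicate 2 and Zscan4f3A replicate 3. Test, median and mean differed in sign in 5 lists, none of them called: the mitochondrially encoded, DNA methylation, telomere, endothelial and adipocyte lists.

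**Figure D3:**
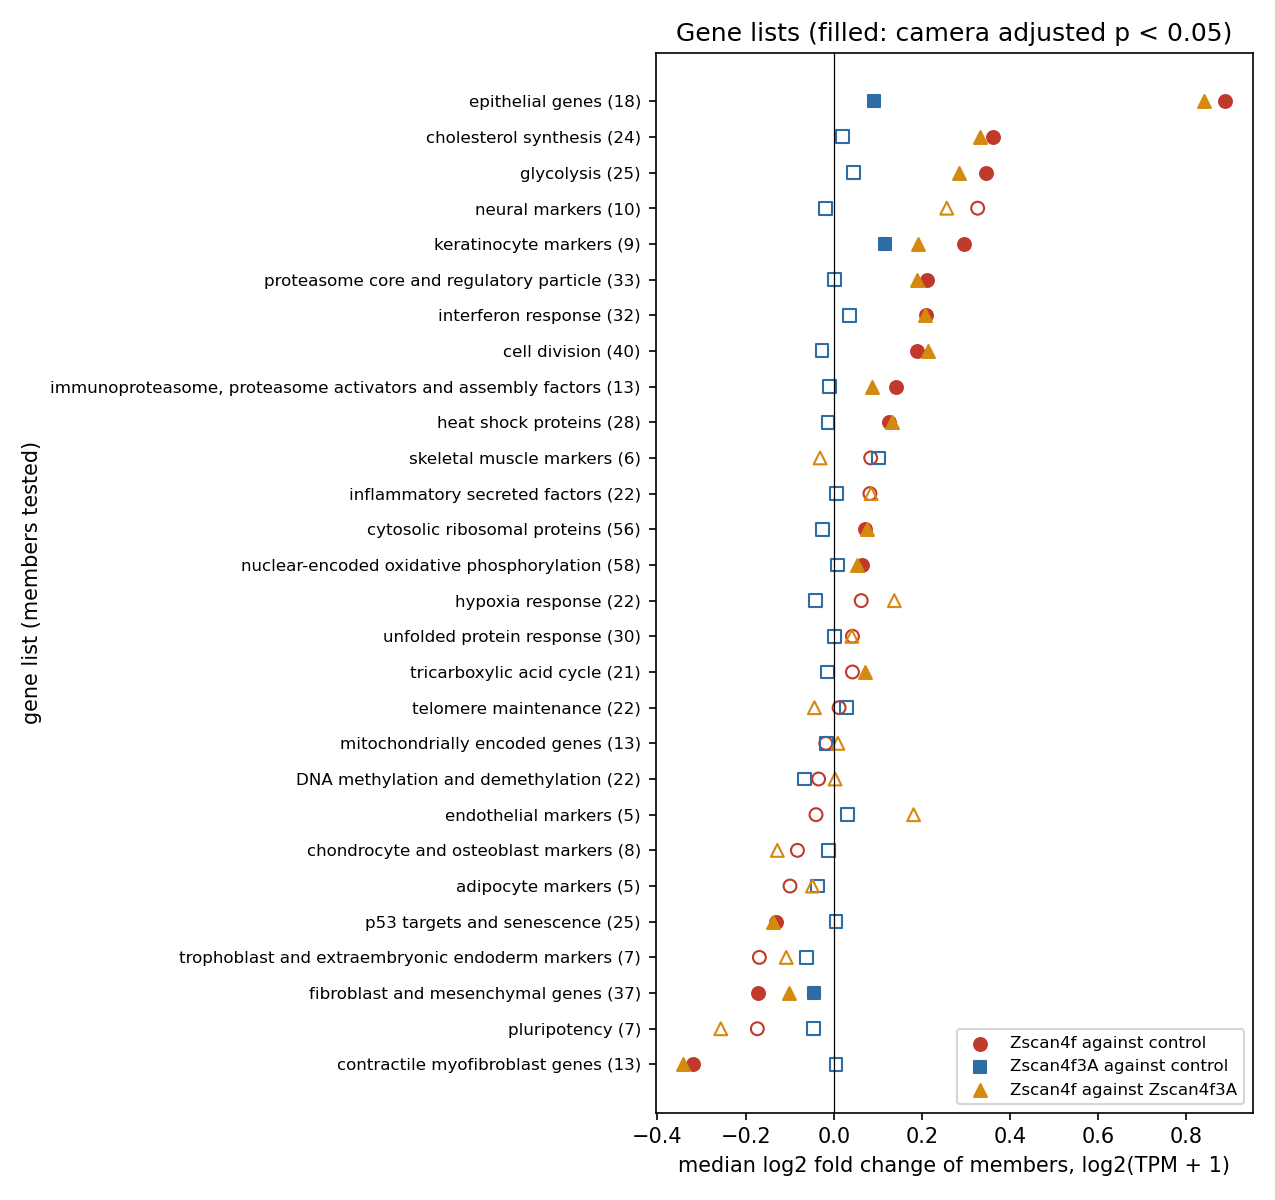
Symbols give the median log2 fold change of the tested members of each of 28 gene lists in the 3 comparisons, with the number of members tested in brackets. Filled symbols passed camera with a preset correlation (14, 3 and 15 lists). The medians for Zscan4f against control and against Zscan4f3A lie close together in the called lists.

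Genes that set Zscan4f apart from both other groups with the same sign numbered 1981, of which 946 were higher and 1035 lower with Zscan4f. Beyond these, 0 genes were called against both groups with opposite signs. Both comparisons use the same Zscan4f libraries, which favours equal signs. Krt8, Klk10, Fdps, Pkm and Psmd14 were among the higher ones and Eln, Loxl1, Tpm2 and Cdh2 among the lower ones. Of 2916 genes changed with Zscan4f against control outside the Zscan4 cluster, 81.4% had a log2 fold change of the same sign with Zscan4f3A. In 100 simulations that kept the Zscan4f effect and left Zscan4f3A unchanged, this share had a mean of 58.7% and a range from 42.5% to 75.5%. The simulations called 4167 genes on average, more than the 2916 of the data, so the shares cover unlike sets of genes. The comparisons with control shared 4 genes: Zscan4f and Klk14, higher in both, and Emx2 and Igfbp3, lower in both. Outside the Zscan4 cluster 3 were shared, and 2 of the 100 simulations gave as many. The simulated counts had a median of 0, a mean of 17.0 and a highest of 1546. They were thus very uneven, and the 2 of 100 is a coarse measure. With the cluster included, independent lists would share 0.262 genes higher and 0.194 lower. Counted with the cluster, shared genes numbered 1 without control replicate 3 and 12 without Zscan4f3A replicate 3. In the latter fit, Zscan4f3A against control also called Zscan4c, Zscan4d, Zscan4e and the unnamed loci RP24-351P7.8 and RP24-96C7.8 of the cluster. Zscan4f3A replicate 3 lists all of these at 0, so 12 is not a count of shared response outside the cluster. Across 15829 genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0303, and 100 simulations of 2 unchanged groups gave a mean of 0.0202 with a range from -0.00914 to 0.0925. Of these genes 64.1% had the same sign in both comparisons, against a mean of 67.4% and a highest of 91.7% in the same simulations. Those simulations hold no Zscan4f effect, so their shares are not what to expect beside one. Since the 3 control libraries cannot be split into parts of at least 2, part of any excess may come from the shared controls.

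**Figure D4:**
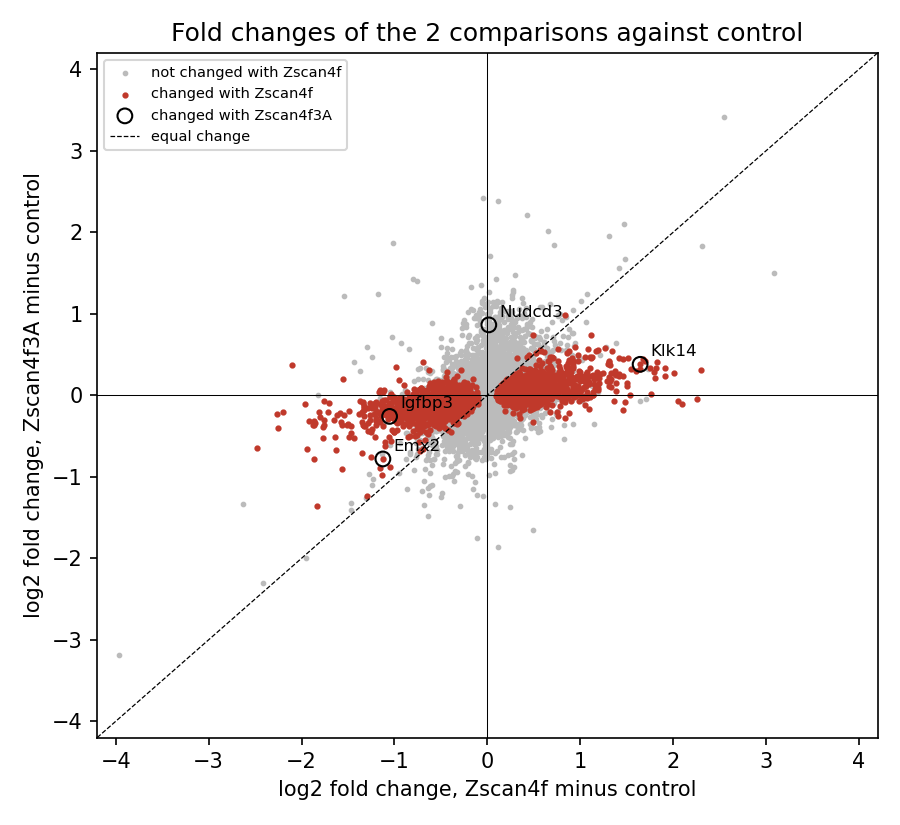
Each point is a gene, with its log2 fold change of Zscan4f minus control on the horizontal axis and of Zscan4f3A minus control on the vertical axis; the Zscan4 cluster is left out. Genes changed with Zscan4f (red) lie near the horizontal axis, and the 4 ringed genes passed the test with Zscan4f3A.

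Zscan4f3A replicate 3 differed from the other libraries in more than depth. Across genes, r between libraries of a group was 0.986 to 0.989, but 0.974 and 0.975 between this library and the other Zscan4f3A libraries. On the second principal component, with 21.3% of the variance, it lay at -39.6 while the other 8 libraries lay between -7.00 and 15.4. The mitochondrial share of TPM ranged from 9.01% to 9.94% over the 9 libraries. Without this library Zscan4f against control gave 3285 genes and Zscan4f against Zscan4f3A 1987.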

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

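The test of the difference between the effects of the 2 overexpressed forms and the splits of the samples were planned. The tests of shared controls, of the transcript level and of activity left in the mutant were chosen only after the result was seen, as were the simulations. The limits of the Zscan4 cluster left out of them were widened after a first run.

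The change against control differed between Zscan4f and Zscan4f3A for 2395 genes by limma's test of the difference itself (1574 without Zscan4f replicate 3), with Krt8, Klk10, Fdps and Pkm higher and Eln, Loxl1 and Tpm2 lower with Zscan4f. The 6 libraries of this comparison make 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many genes (2395), and the highest of the others gave 4. The same holds for Zscan4f against control, where 1 of 10 splits gave as many genes as the real one (2922) and the highest other gave 2, and for Zscan4f3A against control, where 1 of 10 did (5) and the highest other gave 4. For genes changed with Zscan4f against both other groups, 1 of 100 groupings of the 9 libraries, the real one, gave as many (1981), and the highest other gave 3. That is the smallest share 100 groupings can give, and it argues against a chance split of these libraries for that count. It does not cover chance between cultures, since the replicates may be technical. Nor does it tell an effect of Zscan4f from another difference between the groups.

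With Zscan4f3A, 81.4% of the genes changed by Zscan4f had a log2 fold change of the same sign, and Klk14, Emx2 and Igfbp3 were called alike. A lower level of the mutant transcript is argued against for replicates 1 and 2, with summed TPM of Zscan4a to Zscan4f of at least 1076 against at most 724.6 with Zscan4f, and left open for replicate 3, where Zscan4f alone (654 TPM) lay above all Zscan4f libraries (at most 570) and that sum (654) below them (at least 709), and protein was not measured. Shared control libraries stay open: the covariance of the log2 fold changes, 0.0303, lay within the range of 100 simulations of unchanged groups (-0.00914 to 0.0925, 20 as large), while the 81.4% lay above all of 100 simulations with only Zscan4f3A unchanged (highest 75.5%). The latter called 4167 genes on average, a larger set than the one behind the 81.4%. Over all genes outside the Zscan4 cluster 64.1% had the same sign, against a mean of 67.4% in the simulations of unchanged groups. The latter hold no Zscan4f effect, so the 2 shares are not like for like. The excess of the covariance over the simulated mean would correspond to 14.4% of the Zscan4f effect. These simulations, in which a single draw can move many genes together, did not tell it apart from 0. Activity left in the mutant and an effect of overexpression as such cannot be separated, because no group overexpressed another protein, so whether Zscan4f3A keeps part of the effect stays open.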

How the results depend on the processing

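Library quality weights, protein-coding genes alone, the fit of Zscan4f against control without Zscan4f3A replicate 3 and the count of genes changed alike in both comparisons against control were chosen after seeing the data. Of 159 alternatives to 8 counts, 132 stayed within 1.5 times, 23 were lower and 4 higher. Of 1656 alternatives to 84 list tests, 1476 kept direction and side of the threshold, 83 lost and 28 gained a call, 68 uncalled lists changed direction and 1 reversed with a call. Of 8303 alternatives to 467 fold changes of named genes, 7927 kept both, 260 lost and 55 gained a call, 58 uncalled ones changed sign and 3 reversed with a call. Where not stated otherwise, the cause was not tested. A fold change of at least 1.5 left 891 genes for Zscan4f against control, 3 for Zscan4f3A against control and 657 for Zscan4f against Zscan4f3A, since it asks for more. Over the alternatives apart from left-out libraries and that fold, Zscan4f against control reached up to 3398 genes (quality weights), and genes against both other groups ran from 1581 to 2154. For Zscan4f3A against control, no filter gave 3 genes. With the replicate number as a term (replicate block) it gave 1, Zscan4f against control 2504, Zscan4f against Zscan4f3A 1883, and genes changed alike in both comparisons 1. The numbers do not pair the samples: residuals of 9 same-numbered pairs correlated at -0.0792 to 0.0533, others at -0.0481 to 0.054. Genes changed alike numbered 2 with only the 2 groups compared and 2 with no trend. With an estimated correlation camera called 8, 0 and 7 lists in the 3 comparisons. For Zscan4f3A against control it called 1 list with FPKM and 0 with median-of-ratios scaling, quantile normalization, only the 2 groups compared or no trend. The proteasome and glycolysis lists kept their calls for Zscan4f against both other groups under all alternatives run, with adjusted p up to 0.0402 and 0.0178 against control and 0.0494 and 0.019 against Zscan4f3A.

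With 1 library left out, Zscan4f against control gave 2126 to 3285 genes, Zscan4f3A against control 1 (without control replicate 3) to 16 (without Zscan4f3A replicate 3), Zscan4f against Zscan4f3A 1574 (without Zscan4f replicate 3) to 1987, genes against both 1363 to 1775 and genes changed alike 1 (without control replicate 3) to 12 (without Zscan4f3A replicate 3). The genes changed alike include those of the Zscan4 cluster. Lists called numbered 13 to 15, 0 to 2 and 12 to 16. For Zscan4f3A against control the proteasome list had adjusted p from 0.0723 to 0.975, the latter downward without Zscan4f3A replicate 1, and the ribosomal list from 0.0228 (called, upward, without Zscan4f3A replicate 3) to 0.803. For Zscan4f against Zscan4f3A the log2 fold change ran from -0.70 to 3.09 for Zscan4c, from -0.79 to 1.59 for Zscan4d and from -1.07 to 1.58 for Zscan4e, each lowest without Zscan4f3A replicate 3, which lists them at 0. Leaving out 1 library ended 40 calls of named genes and 9 of lists. No scaling moved the median of all genes by more than 0.022 (log2). Without counts, what depth limits can be read only from the lower depth of Zscan4f3A replicate 3 (3.31 gigabases).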

Other observations

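The gene families named here by a shared stem of the gene name, and every other test reported here, were chosen only after the data were seen. The bound of 75% for pseudogenes was written after the result, and its interval was added once the value was known.

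Several gene families moved together with Zscan4f against control by camera among 402 stems, and in the same direction under FPKM, median-of-ratios scaling and quantile normalization. All of these calls were lost with an estimated correlation (adjusted p = 0.73 for Col, Klk, Cdh and Sprr, 0.75 for Tubb). Of 32 genes with the stem Col, collagen chains but for Col4a3bp, 22 were lower and 2 higher (median log2 fold change -0.28, adjusted p = 1.6e-08). Col16a1 fell by 1.01, Col28a1 by 1.10 and Col27a1 by 1.21 on the log2 scale, while Col1a2, a chain of collagen I, rose by 0.25. Of 11 cadherins 8 were lower and 1 higher (adjusted p = 3.3e-04): Cdh1, E-cadherin, rose by 0.61, Cdh2, N-cadherin, fell by 0.88 and Cdh6 fell by 0.98. Among kallikrein-related peptidases 4 of 6 were higher and 0 lower (median 1.37, adjusted p = 7.8e-06), with Klk11 higher by 1.10 (log2) beside Klk10, Klk13 and Klk14. Of 6 Sprr genes, which encode small proline-rich proteins of the cornified envelope, 4 were higher and 0 lower (median 0.90, adjusted p = 0.0074), Sprr1a by 1.05. Of 7 beta-tubulins 6 were higher and 0 lower (median 0.20, adjusted p = 1.1e-04), Tubb4a by 1.14.

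The fall of mt-Atp6 was not shared by its neighbour. The genes mt-Atp8 and mt-Atp6 overlap and lie on 1 transcript, yet mt-Atp8 had a log2 fold change of -0.037 (11827 ± 127 TPM in control, 11528 ± 94.2 with Zscan4f), which argues against a fall of that transcript. A split of reads between overlapping genes by the quantifier is argued against only for mt-Atp8 and mt-Co3, the neighbours that overlap mt-Atp6. They gained 1.90% (SE 1.64) of the signal lost by mt-Atp6 (TPM times length). That test does not cover reads that the quantifier left out or placed elsewhere. In the control libraries alone mt-Atp6 varied 1.72-fold, against at most 1.12-fold for the other 12 mitochondrially encoded genes. The cause of the fall stays open. No other explanation was tested for this gene.

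Zscan4f3A replicate 3 stood apart from replicates 1 and 2 of its group. Lower depth alone is argued against: processed pseudogenes deviated from the mean of replicates 1 and 2 by a median 0.65 (log2) more than protein-coding genes (95% bootstrap interval 0.463 to 0.816). A mislabelled control library is argued against by 654 TPM of Zscan4f, against at most 0.960 in control, and a mislabelled Zscan4f library by a score of 0.190 on a scale from 0 (control) to 1 (Zscan4f), on which each Zscan4f library, held out in turn, scored at least 0.919. Reads shared with processed pseudogenes may have been assigned differently in this library, which stays open: 72.9% of 258 processed pseudogenes lay above the mean (exact 95% binomial interval 67.0 to 78.2), an interval that includes the bound of 75%, while 46.2% of long intergenic non-coding RNA genes did. Both the bootstrap and the binomial interval take the genes of 1 library as independent, so neither measures the spread between libraries. No biological explanation was tested, as the replicates share a group.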
